A study of Homo sapiens with 6 samples.

How the data were processed

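RNA was measured by sequencing in 6 libraries of MCF7, an established human breast cancer line that expresses estrogen receptor alpha. Per the labels' protocols, cells were kept for some days in phenol-red-free medium with 10% carbon-treated serum, which lowers the estrogens in the medium, and were then given 5 nM PPT (propyl pyrazole triol, an agonist selective for estrogen receptor alpha) or the solvent DMSO for 16 h. Total RNA was extracted with TRIzol and 2 µg went into a stranded mRNA library kit, per the labels' protocols. The 6 libraries form 2 groups of 3, DMSO and PPT, and the only comparison is PPT minus DMSO.

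The authors deposited 1 table of raw counts per gene, not normalized, with 36974 genes, their exon coordinates, their summed exon length in bases and a count column for each library. Per the submitters' processing notes, the tools included Trimmomatic 0.36, TopHat2 2.0.13, HTSeq 2.0.0 and DESeq2 1.36.0 with the builds GRCh38 and hg38, and the layout of the deposited count table is the one featureCounts writes, per the file headers. Which tool made the counts, the counting options, the strand setting and the annotation release are not given in the sources used here. The control columns carry the name Mock. They were taken as the DMSO libraries because they are the only columns outside the PPT group and have the same numbers, 1 to 3. The table lists no gene with 0 counts in all libraries, so a gene missing from it had no count in any library or was not in the annotation. In 27 genes the name had been turned into a calendar date, and these names were restored by matching coordinates to GENCODE release 29. Of all genes, 68.4% matched that annotation by name and chromosome, and 93.25% of those had the same start and end. Gene types come from this match, and coordinates are those of the deposited table, on GRCh38. A total of 118 genes had exons on more than 1 chromosome and were left out where positions were compared.

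Among counts from 1 to 20, between 70.8% and 75.4% per library were even, as when both mates of a read pair are counted singly. The deposited counts were therefore treated as read counts that are not independent fragments, and a counting interval made from them is too narrow. It covers counting error only. If strand was not used in counting, reads of overlapping genes on opposite strands cannot be told apart. Of the 130 named genes, 34 share exon sequence with another gene that holds at least 10% of their counts.

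Genes were filtered with filterByExpr at default settings and 21503 were tested. TMM factors scaled the library sizes, and edgeR 4.0.16 (R 4.3.3) fitted the quasi-likelihood test with the group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values come from the cpm function of edgeR with TMM-scaled library sizes and are given as mean ± SD of 3 libraries. Gene lists and the settings above were fixed before the data were examined. There were 24 lists with 721 entries, of which 653 were tested. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list moves on balance in either direction without comparing it with other genes, were alternatives. Camera with an estimated correlation also tests with fewer degrees of freedom, so a setting with each list's estimate held fixed (0 where negative) and the degrees of freedom of the preset test was added after the data were seen.

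Named genes were chosen by a rule set at the same time: the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol, a mean of at least 1 CPM and groups whose TMM-scaled CPM do not overlap, up to 4 called members of each list with the smallest p, and a fixed set that includes ESR1, ESR2, the progesterone receptor gene and known estrogen and interferon genes. Clone-based names were not counted as symbols. By the same rule a list member was also named where its value was needed to describe its list, such as the members against its direction, and these were picked after their values were seen. Lists share some members, among them EGR3, MYC and ESR1.

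The other normalizations were RLE, upper-quartile and library totals only. The other tests were DESeq2 1.42.0 and limma-voom. The other filters were none and a mean CPM of at least 1. A replicate block, leaving out each library in turn, and counts divided by 2 were also run. Library totals only and counts divided by 2 were added after the data were seen. Replicate numbers were shared by the groups, but same-numbered libraries did not deviate together, so the fit without a block is the main one. Within groups, chi-square per gene between libraries ran from 2.52 to 30.4, so no library was a copy of another. The script was tested on simulated counts of 21503 genes with the means and sizes of these libraries, of which 20938 passed the filter. It recovered 41.2% of genes changed by 0.5 and 75.5% of genes changed by 1 on the log2 scale, none with the wrong sign, and 11 of its 122 calls (9.02%) were false. The simulation changed a far smaller share of genes than the 62.3% called in these libraries. Recovery and the false share depend on that share, so these values do not carry over to the main fit. The list test called the 1 changed list and 0 of 20 unchanged lists. The simulation took means and sizes from these libraries, but not the correlation between members of a list. In these libraries that correlation was estimated from -0.101 (aryl hydrocarbon receptor targets) to 0.857 (ribosomal proteins), with 0.263 for the type I interferon-stimulated genes. The simulated list result therefore cannot tell how often lists whose members vary together are called falsely. Further computing used Python 3 with scipy.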

Results

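Gene expression was measured in MCF7 cells, a human breast cancer line that carries estrogen receptor alpha, after 16 h with 5 nM PPT or with the solvent DMSO, in 3 libraries each. PPT is an agonist selective for estrogen receptor alpha. The series is titled for the link between estrogen receptor alpha signalling and the type I interferon response, and the comparison asks which genes differ when the receptor is activated in cells kept with little estrogen. The DMSO libraries held 57003097, 58283542 and 57447096 counts and the PPT libraries 55521243, 57095660 and 55303925. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

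PPT changed the expression of a large part of the genes. Of 21503 genes tested, 6547 rose and 6853 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 13400 in all or 62.3%. Among these, 4351 changed at least 2-fold, 1794 upward and 2557 downward. TMM-scaled CPM did not overlap between the groups in 14744 genes (68.6%), where chance gives 10%. Of the 126 named genes that passed, 124 had TMM-scaled CPM that did not overlap between the groups, the exceptions being MT-CYB and VIM. The naming rule asked for such groups in the largest rises and falls and for the smallest p in lists. This share was therefore largely set by the selection. Among genes with a symbol and at least 1 CPM, the largest rises included EGR3 (an early growth response transcription factor), GATA4 (a developmental transcription factor), CXCL12 (a chemokine), PGR (the progesterone receptor) and IL20 (a cytokine). The largest falls included GLP1R (the glucagon-like peptide 1 receptor), TM4SF1 and TM4SF18 (tetraspanin-like membrane proteins), PSCA (prostate stem cell antigen) and IL1R1 (the interleukin 1 receptor). The first principal component held 78.6% of the variance and separated the groups, and the second (8.36%) separated DMSO replicate 2 from the other 5 libraries. The share of raised genes among those changed was 48.9% and became 37.4% with library totals in place of TMM factors (5100 raised, 8546 lowered), a scaling that moved the median log2 fold change of all genes from -0.0349 to -0.1731. With a mean CPM of at least 1 as the filter, 2618 genes changed at least 2-fold.

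**Figure D1:**
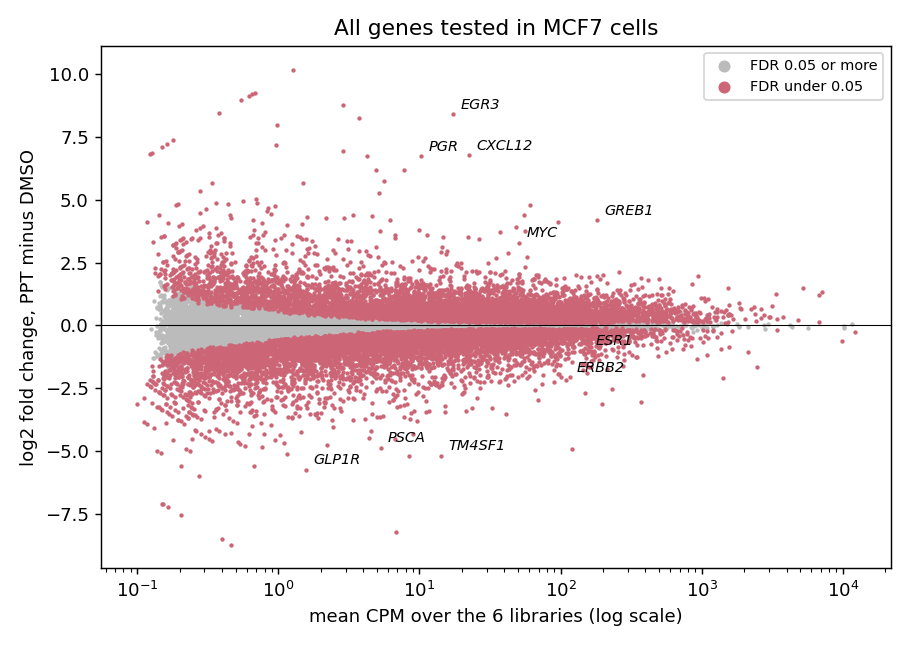
Log2 fold change of PPT minus DMSO (vertical axis) against mean CPM over the 6 libraries (horizontal axis, log scale) for the 21503 genes tested. Each point is a gene, and coloured points are the 13400 with an adjusted p under 0.05. Labels mark 10 named genes.

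Among the largest rises, EGR3 (chromosome 8, 22687659 to 22693302, GRCh38) went from 0.0989 ± 0.0864 CPM (SD, n = 3) in DMSO to 34.8 ± 0.514 CPM in PPT, a log2 fold change of 8.42 ± 0.202 (SE). Without DMSO replicate 3, where most of its DMSO counts lay, the value was 9.39. CXCL12 (chromosome 10, 44370165 to 44386493) rose from 0.404 ± 0.103 to 44.9 ± 1.94 CPM, a log2 fold change of 6.79 ± 0.118 with an adjusted p of 1.233e-09 from edgeR. PGR (chromosome 11, 101029624 to 101130524) rose from 0.188 ± 0.0392 to 20.5 ± 1.38 CPM, a log2 fold change of 6.75 ± 0.134. Lower in level were GATA4 with a log2 fold change of 6.95, IL20 with 6.19, PDLIM3 with 6.17, KCNQ5 with 5.75 and SDK2 with 5.29. The pseudogene SUB1P1 had 5.69, or 6.39 without DMSO replicate 1. Its reads may not be separable from those of its parent gene SUB1. For BLK, a tyrosine kinase of B cells, the DMSO libraries held 2 counts in all, both in DMSO replicate 3, and the PPT libraries 921, a ratio of 474 with a 95% counting interval from 131 to 3920 (exact binomial). The fitted log2 fold change of BLK was 8.76, or 11.34 without DMSO replicate 3, and depends on the prior count. BLK and EGR3 each share exon sequence with a noncoding gene on the other strand.

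Among the largest falls, PSCA (chromosome 8, 142670308 to 142682724) went from 10.3 ± 0.0721 to 0.350 ± 0.102 CPM, a log2 fold change of -4.87 ± 0.159. IL1R1 (chromosome 2, 102064544 to 102179874) went from 12.99 ± 0.400 to 0.560 ± 0.233 CPM, a log2 fold change of -4.53 ± 0.192. GLP1R, at 3.12 CPM in DMSO and 0.0568 CPM in PPT, had -5.74, and -7.23 without PPT replicate 1. TM4SF18 and TM4SF1 on chromosome 3 had -5.19 each. Their DMSO levels were spread (16.3 ± 8.51 and 27.7 ± 14.1 CPM) because DMSO replicate 2 was higher than the others. KLHDC7A had -4.75, CHRD (chordin, a BMP antagonist) -4.47, VTCN1 (an immune checkpoint ligand of the B7 family) -4.32 and ANKRD35 -4.24. TM4SF1-AS1, the antisense gene next to TM4SF1, had -4.68. It shares exon sequence with TM4SF1 on the other strand, as PSCA does with JRK and TM4SF18 with a noncoding gene, so their counts are uncertain if strand was not used.

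Known estrogen-induced genes rose with PPT: 44 of 48 tested members had higher levels, 1 had lower and 3 did not pass, with 44 up and 1 down when adjusted over the list alone. The median log2 fold change was 1.862 (camera, adjusted p = 5.544e-16), and the adjusted p was 0.1103 with an estimated correlation. GREB1, a growth regulator bound by the receptor, rose from 18.9 ± 1.22 to 343.8 ± 2.23 CPM, a log2 fold change of 4.18 ± 0.0568 and the smallest adjusted p of the list (3.613e-10, edgeR). TFF1 (trefoil factor 1) had a log2 fold change of 1.95, PDZK1 2.56 and SIAH2 2.74. MYC, a transcription factor of growth and ribosome production, had 3.29, and cyclin D1 (CCND1) had 0.57. RAB31 was the member that fell (-0.24), a call lost with DESeq2 and without DMSO replicate 1 or 3 or PPT replicate 2 or 3. CYP26B1 (-0.84), FHL2 (0.12) and CA12 (0.15) did not pass the threshold.

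Known estrogen-repressed genes fell: 25 of 28 tested members had lower levels, 0 were higher and 3 did not pass (SMAD6 at -0.20, KRT15 at 0.10 and TRIM29 at 0.47), with 25 down and 0 up when adjusted over the list alone. The median log2 fold change was -1.446 (camera, adjusted p = 2.186e-09), and the adjusted p was 0.1103 with an estimated correlation. BCAS1 went from 660.3 ± 79.7 to 79.6 ± 2.17 CPM, a log2 fold change of -3.05 ± 0.0820. The growth factor receptor gene ERBB2 fell from 187.4 ± 6.68 to 45.0 ± 0.745 CPM, a log2 fold change of -2.06 ± 0.0459, and the cell cycle regulator CCNG2 fell by 1.57 on the log2 scale. Estrogen receptor alpha itself (ESR1; chromosome 6, 151656691 to 152129619) fell from 208.4 ± 24.04 to 105.6 ± 1.94 CPM, a log2 fold change of -0.98 ± 0.0734 (edgeR, adjusted p = 2.126e-06). ESR2, encoding estrogen receptor beta, was at 3.41 ± 0.275 CPM in DMSO and 4.22 ± 0.292 CPM in PPT. Its adjusted p of 0.04188 was lost in 10 alternatives, among them DESeq2 (0.08574) and leaving out DMSO replicate 2 or 3 or any PPT replicate (0.0545 to 0.1393), and the gene shares exons with a noncoding gene on the same strand.

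**Figure D2:**
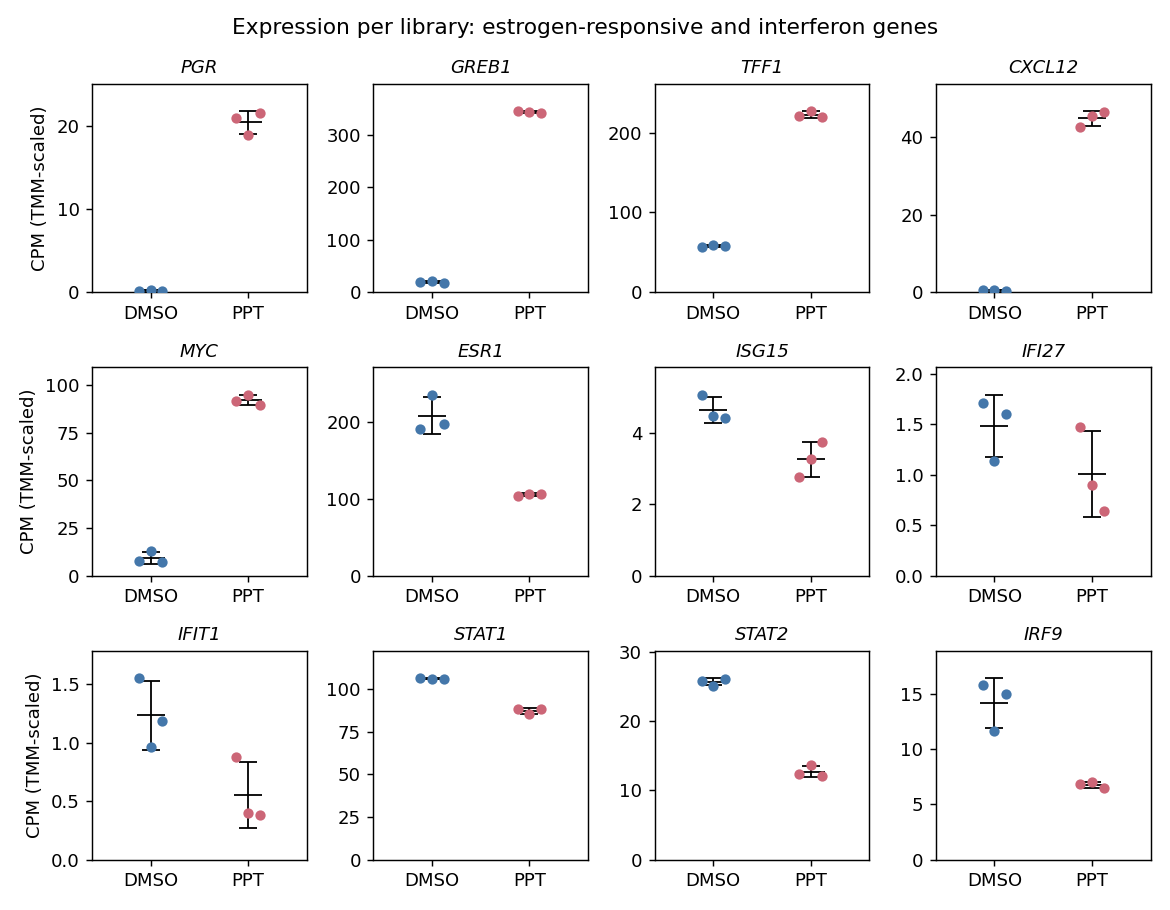
TMM-scaled CPM (vertical axes, each starting at 0) of 12 genes in the 3 DMSO and 3 PPT libraries. Points are libraries, horizontal marks the mean and bars the SD. PGR, GREB1, TFF1, CXCL12 and MYC were higher in every PPT library, and ESR1, ISG15, STAT1, STAT2 and IRF9 lower.

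The type I interferon-stimulated genes moved mostly down. Of 62 tested members, 31 fell, 7 rose and 24 did not pass, with 31 down and 7 up when adjusted over the list alone. The median log2 fold change was -0.501 (camera, adjusted p = 0.005278), and the adjusted p was 0.6993 with an estimated correlation. Among members with a clear level, STAT2, a transcription factor that carries the type I interferon signal, fell from 25.7 ± 0.488 to 12.7 ± 0.821 CPM, a log2 fold change of -1.01 ± 0.0645 (edgeR, adjusted p = 7.174e-07). Its partner IRF9 fell from 14.1 ± 2.24 to 6.76 ± 0.275 CPM, a log2 fold change of -1.06 ± 0.116, and STAT1 from 106.0 ± 0.214 to 87.3 ± 1.81 CPM, a log2 fold change of -0.28. PARP10 fell by 1.45 and the guanylate-binding protein gene GBP2 by 2.58 on the log2 scale. MX1, an antiviral GTPase, fell by 0.92 and the ubiquitin-like modifier ISG15 by 0.51. IRF9, STAT1, PARP10, MX1, ISG15 and OAS1 share exon sequence with other genes that hold at least 10% of their counts. The antiviral genes IFI6 (-1.08), IFIT1 (-1.16), IFIT3 (-0.60) and OAS1 (-1.358) passed the threshold at levels of at most 1.23 CPM, and the calls of IFIT1, IFIT3 and OAS1 were lost without DMSO replicate 1, PPT replicate 2 or PPT replicate 3. The call of IFIT3 was also lost without DMSO replicate 2 and that of OAS1 without DMSO replicate 3. In these settings with a library left out the log2 fold change ran from -0.963 to -0.94 for IFIT1, -0.625 to -0.479 for IFIT3 and -1.443 to -0.997 for OAS1. The adjusted p of IFIT3 was also 0.1328 with DESeq2, 0.0655 with the replicate block and 0.05518 without a filter, and that of OAS1 was 0.06421 with DESeq2. Without PPT replicate 1, OAS1 had -2.001. IFI27 (log2 fold change -0.57, adjusted p = 0.1265) and IRF7 (-0.31, adjusted p = 0.1001) did not pass. IFI27 passed without DMSO replicate 2 (adjusted p = 0.01637) and without PPT replicate 1 (0.0217), and IRF7 with library totals only (-0.45, adjusted p = 0.02834). The members that rose, named for this and not for their level, were HERC5 (3.57) and HERC6 (2.31), neighbours on chromosome 4, PNPT1 (1.33), EIF2AK2 (0.41), IFIH1 (0.34), PLSCR1 (0.33) and TRIM14 (0.26). Of the list, 15 tested members lay below 1 CPM. DMSO replicate 2 stood apart from the other libraries, and without it 39 of 65 members fell and 9 rose. IFNB1, the interferon beta gene, had no entry in the count table.

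Genes of interferon sensing and signalling fell as a list (23 tested, 14 down, 3 up, median log2 fold change -0.348; 15 down and 3 up when adjusted over the list alone). The camera adjusted p was 0.02705, and the adjusted p was 0.2746 with an estimated correlation. The signalling regulator SOCS3 fell by 2.08, the kinase gene IKBKE by 0.94 and the adaptor gene MAVS by 0.57 on the log2 scale, and TRAF3, another adaptor, rose from 6.79 ± 0.666 to 17.4 ± 0.945 CPM. Genes of MHC class I antigen presentation did not pass as a list (20 tested, 9 down and 4 up over all genes and over the list alone, camera adjusted p = 0.2745). The MHC class I antigen presentation median of -0.446 lay at percentile 0.21 of 10000 random lists matched on mean expression. Random genes were drawn independently, here and for the other lists. Members that vary together (estimated correlation 0.299 for MHC class I) can therefore make the percentile too extreme. That MHC class I median was -0.257 without PPT replicate 3 and -0.303 with a mean CPM of at least 1. TAPBP (-0.91), HLA-E (-0.70), TAP1 (-0.80) and IRF1 (-1.26) fell and CANX rose by 0.70. B2M (-0.11, adjusted p = 0.372) and HLA-A (0.09, adjusted p = 0.5878) did not pass. Without DMSO replicate 2 the B2M value was -0.21 with an adjusted p of 0.0004942. HLA genes share sequence with each other, and their counts are uncertain.

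Growth-related lists rose. All 46 tested members of ribosome biogenesis were higher (median log2 fold change 1.271; camera, adjusted p = 5.027e-20), and this was the list whose call held with an estimated correlation (adjusted p = 0.03378). NOLC1 rose by 1.85, NOP56 by 1.89, PUS7 by 1.98 and LYAR by 2.14 on the log2 scale. Of 52 DNA replication genes, 50 rose and 1 fell (median 1.109; camera, adjusted p = 3.758e-16; adjusted p = 0.1616 with an estimated correlation), with CDC45 at 1.39, ORC6 at 1.37 and MCM6 at 1.33. Of 42 mitosis genes, 41 rose and 0 fell (median 0.613; camera, adjusted p = 6.676e-11; adjusted p = 0.4219 with an estimated correlation). MKI67, a marker of cycling cells, went from 2028 ± 300.7 to 3221 ± 88.2 CPM (log2 fold change 0.67), and MAD2L1 had 1.20. The ribosomal protein genes rose less (26 of 37 up, 0 down; median 0.296; camera, adjusted p = 2.719e-05; adjusted p = 0.6993 with an estimated correlation), with RPS14 at 0.95 and RPL35 at 0.68, and 18 up and 1 down with library totals only. The median of the ribosomal protein list lay at percentile 89.0 of 10000 random lists matched on mean expression (5th to 95th percentile 0.022 to 0.342), so its rise was within the range of equally expressed genes. Heat shock and chaperone genes rose (18 of 21 up, 2 down; median 0.865; camera, adjusted p = 1.342e-06; adjusted p = 0.06027 with an estimated correlation), with HSPD1 at 1.48, HSPE1 at 1.29 and CACYBP at 1.22. HSPD1 and HSPE1 share exon sequence. Counts adjusted over each list alone were the same for these lists, except that 42 mitosis genes rose.

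The replication-dependent histone genes, whose mRNAs lack poly(A) tails for the most part, fell (12 of 17 down, 0 up; 13 down over the list alone; median -0.83; camera, adjusted p = 0.002583; adjusted p = 0.1103 with an estimated correlation), with HIST1H2AC at -1.53 and HIST2H2BE at -1.67. Which histone mRNAs the mRNA library kit read, those with or those without tails, was not tested. Whether it kept mRNAs without tails equally in both groups was not tested either. The fall therefore need not hold for the mRNAs without tails. The share of ribosomal RNA also fell (1.28% in DMSO, 0.753% in PPT), while of 94 snoRNA genes 49 rose and 0 fell. Luminal identity genes fell (15 of 22 down, 3 up over all genes and over the list alone; median -0.517; camera, adjusted p = 0.002636; adjusted p = 0.3578 with an estimated correlation), with the transcription factor genes GATA3 at -1.27, SPDEF at -1.40 and ELF3 at -2.11 and the keratin gene KRT7 at -1.70. Without DMSO replicate 2, 5 luminal genes rose. ELF3 and KRT7 share exon sequence with noncoding genes. Glycolysis and hypoxia genes were split (18 of 31 up, 7 down over all genes and over the list alone). Their camera adjusted p was 0.03542, and it was 0.2924 with an estimated correlation, 0.07294 with a mean CPM of at least 1 and 0.06362 with library totals only. LDHA rose by 0.98 and SLC2A1 by 1.13, and NDRG1 (-2.23) and ENO1 (-0.65) fell.

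**Figure D3:**
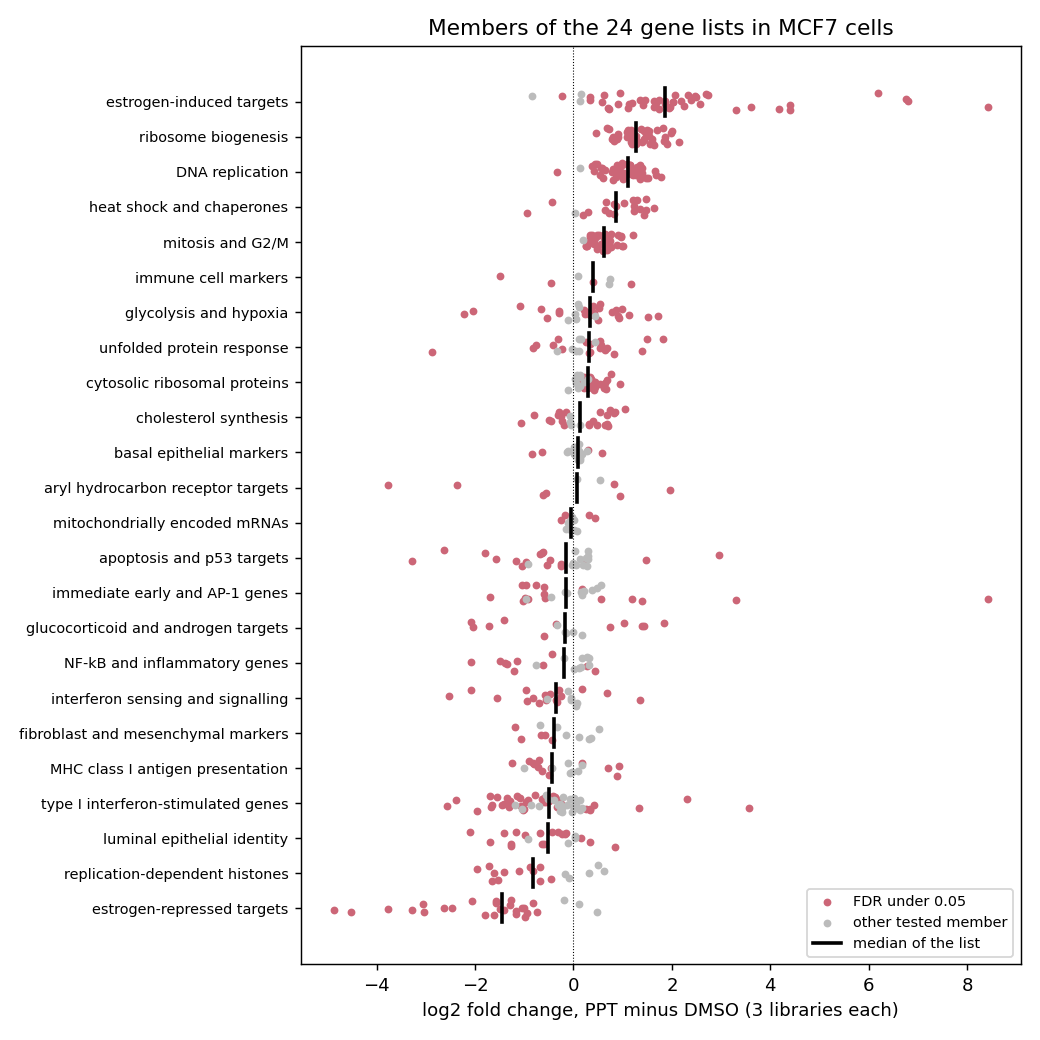
Log2 fold change of PPT minus DMSO (horizontal axis) for the tested members of the 24 gene lists (vertical axis, sorted by median). Each point is a gene, coloured where its adjusted p was under 0.05, and black marks the list median, which ran from -1.446 to 1.862.

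The other lists did not pass with camera. Of 27 unfolded protein response genes 14 rose and 6 fell (adjusted p = 0.05711, and 0.01679 without DMSO replicate 2), with MANF at 0.83 and HERPUD1 at -0.82. The unfolded protein response median of 0.322 lay at percentile 97.34 of random lists matched on mean expression, and was 0.184 with library totals only. Of 27 genes in the cholesterol synthesis list 13 rose and 10 fell (adjusted p = 0.4652), with FDFT1 at 1.05 and SQLE at 0.71. That list also holds the fatty acid genes SCD (-1.06) and FASN (-0.81), so its counts do not describe cholesterol synthesis alone. Of 19 NF-kB genes 2 rose and 8 fell (adjusted p = 0.2683), with BCL3 at -2.08 and NFKBIA at -1.21. Of 30 apoptosis and p53 targets 4 rose and 14 fell (adjusted p = 0.2683), with TP53INP1 at -3.29, BMF at -2.64, SUSD6 at -1.57 and BCL2L1 at -1.17. Without DMSO replicate 2, 10 of these targets rose. Of 26 immediate early genes 6 rose and 10 fell (adjusted p = 0.7356), and the median (-0.155) and mean (0.232) had opposite signs, with EGR3 and MYC raised while IER2 (-0.98) and JUNB (-0.92) fell. The immediate early median was -0.1 without PPT replicate 1, -0.003 with counts divided by 2 and 0.005 without DMSO replicate 2, so its sign turns on that library. IER2, JUNB and BCL2L1 share exon sequence with genes on the other strand. Of 16 glucocorticoid and androgen targets 5 rose and 6 fell (adjusted p = 0.8564), with FKBP5 at 1.43, TSC22D3 at -2.08 and TMPRSS2 at -1.73. Of 9 aryl hydrocarbon receptor targets 3 rose and 4 fell (adjusted p = 0.9049; median 0.076, mean -0.328), with SLC7A5 at 1.97 and UGT1A6 at -2.36, whose exons are shared with the other UGT1A genes. The sign of the aryl hydrocarbon receptor median was not stable: it ran from -0.118 without PPT replicate 2 to 0.414 without DMSO replicate 2, and was -0.064 without DMSO replicate 3, -0.054 without DMSO replicate 1, -0.226 with DESeq2 and -0.583 with a mean CPM of at least 1. Adjusted over the list alone, these counts were the same except that 15 apoptosis and p53 targets fell.

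Markers of other cell types and signs of RNA quality were counted in the same way. Of 18 basal epithelial markers 2 rose and 2 fell (camera, adjusted p = 0.5817), with CDH3 at -0.63 and OXTR at 0.59, and their median of 0.097 was -0.044 with library totals only and 0.027 without PPT replicate 1. Of 12 fibroblast markers 0 rose and 5 fell (adjusted p = 0.3868), with FN1 at -1.18 and COL1A1 at -1.06, and 3 fell without DMSO replicate 3, PPT replicate 2 or PPT replicate 3. Of 7 tested immune cell markers 2 rose and 2 fell (adjusted p = 0.8564), with CD19 at 1.17, CD8A at 0.40, NKG7 at -1.50 and CD68 at -0.45, and CD68 and CD19 share exons with genes of higher count. The call of CD8A (adjusted p = 0.03989) was lost with upper-quartile factors (0.06774), with library totals only (0.1357) and without DMSO replicate 1 or 3 or any PPT replicate (0.07817 to 0.1296). A single immune marker rose, 1 of 7, without DMSO replicate 1, DMSO replicate 3, PPT replicate 1 or PPT replicate 3. The immune marker with the highest level, LCP1, had a log2 fold change of 0.73 (adjusted p = 0.1331). DMSO replicate 2 held 1267 counts of LCP1 against 5230 and 5188 in the other DMSO libraries, and without it the log2 fold change was 0.33 (adjusted p = 1.89e-07) and 3 immune markers rose. LCP1 also passed with the replicate block (0.03958) and without a filter (0.0339). Of 13 mitochondrially encoded mRNAs 2 rose and 2 fell (adjusted p = 0.8564), with MT-ND2 at 0.31 and MT-CO1 at -0.26, and with library totals only 8 fell. Without DMSO replicate 3, 6 of them fell, and 1 fell without DMSO replicate 1, PPT replicate 1 or PPT replicate 2. The counts adjusted over each list alone were the same. Counts on the mitochondrial genome made up 9.02% ± 0.560 of the DMSO libraries and 7.47% ± 0.250 of the PPT libraries (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Genes typed as ribosomal RNA or mitochondrial ribosomal RNA took 1.28% ± 0.0773 and 0.753% ± 0.00872 (exact permutation p = 0.1). Mitochondrial ribosomal RNA counts toward this share and toward that of the mitochondrial genome. Long noncoding genes took 1.64% ± 0.180 and 1.07% ± 0.01 (exact permutation p = 0.1). These shares moved with the treatment.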

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

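Library totals only, counts divided by 2 and camera with the estimated correlation held fixed were chosen after the data were seen. Over the 15 alternatives the count of changed genes stayed within 1.5 times of 13400, and all calls shared with the main test had the same sign. It was 12663 with DESeq2, 13330 with limma-voom, 13614 without a filter, 11434 with a mean CPM of at least 1 and 12931 with counts divided by 2, and leaving out 1 library gave 11958 to 14731. The count changed at least 2-fold fell to 2618 with a mean CPM of at least 1, a setting that tests fewer weakly expressed genes. The replicate block gave 12924 genes and moved no camera call of the 24 lists. Same-numbered libraries had deviations that correlated at -0.007, -0.006 and -0.006, so the numbers share only a name. With an estimated correlation the camera adjusted p became 0.1103 for the estrogen-induced list, 0.1103 for the estrogen-repressed list and 0.6993 for the interferon-stimulated list. That setting also lowers the degrees of freedom, and of the 11 calls it ended, 2 were of lists estimated at or under the preset correlation (histones and heat shock). With each estimate held fixed and the degrees of freedom kept, 6 of 12 calls stayed, among them both estrogen lists (0.001594 each), and the interferon-stimulated list had 0.6097. For MHC class I, fry gave 0.03298 where camera gave 0.2745, and fry does not compare a list with other genes. Fry also passed the NF-kB (3.567e-05), aryl hydrocarbon receptor (0.0006698), unfolded protein response (0.002727), cholesterol synthesis (0.02674) and apoptosis and p53 (0.02674) lists, which camera did not. Leaving out 1 library, MHC class I ranged from 0.0501 to 0.4006 and the interferon-stimulated list from 0.000412 to 0.01272. Directions turned only for values that passed in neither setting. For immune cell markers the adjusted p was then 0.9366 without PPT replicate 1 and 0.9572 with fry, and for immediate early genes 0.9882 without DMSO replicate 2. Glucocorticoid and androgen targets had 0.1669 with fry. Aryl hydrocarbon receptor targets had 0.9906 with upper-quartile factors, 0.9882 without DMSO replicate 2, 0.9366 without PPT replicate 1 and 0.9127 with library totals only. Mitochondrially encoded mRNAs had 0.8719 without DMSO replicate 1, 0.9882 without DMSO replicate 2 and 0.9366 without PPT replicate 1. Over the settings that leave out 1 library, the adjusted p ran from 0.6575 to 0.9366 for immune cell markers, 0.5291 to 0.9882 for immediate early genes, 0.8516 to 0.9882 for aryl hydrocarbon receptor targets and 0.375 to 0.9882 for mitochondrially encoded mRNAs. The log2 fold change of B2M was 0.008 without DMSO replicate 1, and ran down to -0.206 without DMSO replicate 2. That of HLA-A was -0.063 without DMSO replicate 2 and -0.049 with library totals only, and reached 0.212 without DMSO replicate 1. The cause was not tested. Of the 130 named genes, 118 kept their direction and their side of the threshold in all alternatives that gave them a value. Over all lists and alternatives, 19 values lost the threshold, 7 reached it and 323 stayed, and for the named genes 43 lost it, 4 reached it and 1894 stayed. Depth limits what can be called among genes below 1 CPM, where the counts of a library are few.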

Other observations

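Sets of protein-coding genes that share the letters before the first digit of their symbols, and so can hold genes of other function, were tested after the data were seen, as were, below, the tests of single noncoding genes and gene types, the interferon list with its correlation held fixed, and the tests on DMSO replicate 2 other than the first. The interferon list without DMSO replicate 2 and with an estimated correlation were planned settings, set against that pattern only after their results were seen. Of 231 such sets with at least 8 members, not recomputed under the other scalings, 39 passed with camera at the preset correlation and 0 with an estimated correlation. Genes with the letters of mitochondrial ribosomal proteins rose (41 of 49 MRPL and 24 of 29 MRPS genes), as did those with the letters of nucleoporins (21 of 22 NUP genes), mitochondrial import (13 of 14 TIMM genes), RNA polymerase subunits (21 of 30 POLR genes) and the CCT chaperonin (7 of 8 CCT genes). For these sets the adjusted p was 0.4224 to 0.4442 with an estimated correlation. Of 32 genes with the letters COL, which include COL4A3BP, 14 fell and the others did not pass (camera, adjusted p = 0.01772, and 0.5581 with an estimated correlation), and of 10 genes with the letters IRF, which include IRF2BP1, IRF2BP2 and IRF2BPL beside the interferon regulatory factors, 7 fell (camera, adjusted p = 0.008287, and 0.4224 with an estimated correlation).

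Genes outside the named set, chosen after their values were seen, included the nuclear noncoding RNAs MALAT1 and NEAT1, which made up 0.392% ± 0.113 and 0.239% ± 0.0802 of the DMSO libraries and 0.115% ± 0.00778 and 0.0505% ± 0.00175 of the PPT libraries (SD, n = 3; exact permutation p = 0.1 for each). The imprinted neighbours DLK1 and MEG3 on chromosome 14 had log2 fold changes of -3.65 and -3.22. Both also differed between the DMSO libraries. DMSO replicates 1, 2 and 3 held 727, 227 and 727 counts of DLK1 and 2087, 584 and 2348 of MEG3. The PPT libraries held 30 to 48 and 144 to 170. Of 794 processed pseudogenes 407 rose and 66 fell. In 682 pairs of pseudogene and parent, log2 fold changes correlated across genes at a Spearman rho of 0.311, and genes are not independent replicates. Of 94 snoRNA genes 49 rose and 0 fell. Some of them, such as SNORD86 and SNORD57, share exon sequence on the same strand with NOP56, which rose by 1.89 on the log2 scale. Their counts may hold reads of such genes, which was not tested. Other noncoding classes went the other way: of 319 lincRNA genes 37 rose and 146 fell, and of 587 antisense genes 109 rose and 212 fell. Over all 21503 genes tested, 6547 rose and 6853 fell. The gene classes were not recomputed under the alternatives.

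Of the 62 interferon-stimulated genes tested 31 fell and 7 rose, and for the lower median weak expression, a single library and shared variation were weighed. Their median log2 fold change of -0.501 lay at percentile 0.0 of 10000 random lists matched on mean expression, which argues against a general fall of weakly expressed genes. The random lists had a median of -0.053. Their genes were drawn independently, so the percentile leaves out shared variation. With a mean CPM of at least 1 as the filter, 47 members were tested, 24 fell and 6 rose. The median was then -0.346 (camera, adjusted p = 0.03553), so weakly expressed members added to the size of the fall. Without DMSO replicate 2 the median was -0.569 with a camera adjusted p of 0.000412. That library had the lowest mean level of the list among the DMSO libraries (-0.211, against 0.154 and 0.0571, log2 relative to the DMSO mean). Leaving it out was bound to widen the difference, so this setting cannot test a single library as the cause. Without DMSO replicate 1, the highest, the median was -0.401 (camera, adjusted p = 0.01272), so the fall did not rest on that library alone. With an estimated correlation the adjusted p was 0.6993 (0.000412 to 0.6993 over the alternatives), which mixes shared variation with fewer degrees of freedom, but with the estimate held fixed and the degrees of freedom kept it was 0.6097, so that members varying together within groups may leave the list with less evidence than its size gives, and this stays open. An effect of the receptor on interferon signalling is a further hypothesis that these libraries do not separate from other effects of the treatment.

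DMSO replicate 2 stood apart: 73 genes with at least 5 CPM differed in it at least 2-fold from the log2 mean of the other DMSO libraries. The gap between those other libraries was limited to under 0.5 on the log2 scale. No other library had such a gene against the other 2 of its group. Of these genes 55 were lower in DMSO replicate 2, such as CORO1A, BASP1 and AGR2, and 18 higher, such as INHBE, GAB2 and HMOX1, all picked after their values were seen. Of the 73 genes, 31.5% lay between the other DMSO libraries and the PPT mean (exact 95% interval 21.1% to 43.4%; 26.1% of 234 genes with no limit on the gap and at least 1 CPM), which fell between the bounds set beforehand and decided nothing; the 5 CPM and gap limits were not part of those bounds. A later test read the share of PPT-treated RNA from 56 genes raised at least 8-fold and gave a median of 0.0248% (bootstrap interval -0.448% to 0.595%), where a 2-fold fall by dilution needs 50%, so admixture of such RNA is argued against. Noncoding genes were shifted by -0.003 against protein-coding genes (-0.033 to 0.02), which argues against more nuclear RNA in general, although MALAT1 and NEAT1 were highest in this library (0.52% and 0.33%); whether a culture of other composition or stress state could account for the 73 genes cannot be told apart, since the labels name no culture.

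Genes next to each other on a chromosome changed together. BLK, GATA4 and SUB1P1 lay within 11494001 to 11790386 on chromosome 8 and rose, and TM4SF18, TM4SF1 and TM4SF1-AS1 within 149318498 to 149386583 on chromosome 3 fell. The chromosome 3 genes share the start of their symbols, and TM4SF1 overlaps TM4SF1-AS1, so overlap or family is not set aside for them. Across pairs whose spans do not overlap and lie within 200 kb, the Spearman rho of log2 fold changes across genes was 0.144 (9370 pairs, highest of 1000 permutations 0.0367). Genes are not independent replicates. The permutation p was 0.001, the smallest these permutations can give, here and for the next values. This rho argues against reads shared by overlapping genes as the whole cause. In 4804 pairs whose spans overlap rho was 0.583. Some shared reads there seem to be counted for more than 1 gene. UGT1A8, UGT1A9, UGT1A5 and UGT1A3 share exons with UGT1A6 and had 4289, 4293, 4290 and 4291 counts. How much of the rho of 0.583 comes from shared reads was not tested. For divergent neighbours 10 to 200 kb apart rho was 0.104 (1328 pairs, highest permuted 0.0909, a narrow margin). This argues against transcription past gene ends as the whole cause. Without pairs sharing the first 3 letters of their symbols rho was 0.122 (highest permuted 0.0395). With both genes also protein-coding it was 0.101 (highest permuted 0.0444). These values argue against gene families as the whole cause, but family members whose first letters differ stay in the pairs. A candidate explanation is regulation shared by a region, a hypothesis that these counts do not test directly.

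Only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many as 13400 changed genes, and the highest of the other splits gave 0 with edgeR, with 61 to 244 genes at an unadjusted p under 0.05 where the real split had 14184. Each of the other splits mixes PPT and DMSO libraries in both groups, so the treatment difference enters their spread within groups. Their low counts were therefore fixed by the design and do not measure what chance alone gives. With 10 splits no share under 0.05 can be reached.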
